A study of Mus musculus with 2 samples.

How the data were processed

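Nuclei from the medial prefrontal cortex of male mice were profiled with the 10x Genomics 3' v3.1 chemistry, which reads a tag near the 3' end of each transcript and counts molecules by a unique molecular identifier (UMI). Per the labels, tissue of 4 mice was pooled per genotype and gave 1 library for Npas2 knockout mice and 1 for wild-type littermates. Per the submitters' processing notes the genome build was mm10. The aligner, the counting and clustering tools, the filters on nuclei, the treatment of doublets and the names of cell types are not given in the sources used here.

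The authors deposited average normalized expression per gene, a linear signal that is never negative, for each genotype and for 23 numbered clusters that pool both genotypes. Each of these columns summed to 10000 over 31053 genes, so a value is the mean over nuclei of a gene's counts per 10000 counts of a nucleus. The table holds no values per nucleus and no counts. Of the gene identifiers, 30902 were found in GENCODE release M21, from which positions on the same build were taken, and 36 rows carried a symbol without an identifier.

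The number of nuclei behind each column was computed from the table. A weighted sum of both genotype columns equals a weighted sum of the cluster columns, and the weights were whole numbers of nuclei to within 6.1e-08 nuclei. They gave 12739 nuclei, 7161 in the library labelled knockout and 5578 in the library labelled wild-type. In genes listed in at most 10 clusters, the signal of a cluster can equal exactly 1 UMI in 1 nucleus. Its size then gives the depth of that nucleus, and the genotype columns tell its library. Of 7339 genes searched, 4154 could be divided between the libraries in a single way, and 9336 values lay within 0.0001 of a whole number of UMIs. Each was weighted by the reciprocal of its depth to estimate the share of each cluster's nuclei per library, with 95% intervals from 1000 resamplings of genes. The estimated mean depth was 3274 UMIs per nucleus in the library labelled knockout and 4034 in the library labelled wild-type.

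The comparison used the log2 ratio of the library labelled knockout over the library labelled wild-type, with a pseudocount of 0.01, which understates the change of low genes. Genes were kept at a mean of both libraries of at least 0.0461, the median of the 24005 genes above 0, which left 12003. Ratios of means, without the pseudocount, carry 95% counting intervals (Clopper-Pearson) on UMI numbers estimated from the depth and reduced for its spread between nuclei. Intervals and shares cover counting error only, since nuclei are not replicates. With 1 library per genotype there is no test and no p-value, and no difference has a replicate check. The table holds no counts, so the Poisson and binomial intervals planned for counts were replaced by these.

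Named genes followed a rule fixed before the data were examined. It took Npas2, the 12 largest increases and 12 largest decreases above the floor, every member above the floor of the core clock and dopamine lists, and up to 4 members of each other list. Genes without an assigned name were counted but not named, and some genes that the rule takes are not reported here. Th, Ddc, Gch1 and Drd3 fell below the floor and were named after their values were seen. List medians were set against 10000 random lists of the same size matched on mean expression in 20 bins, for lists with at least 3 members above the floor. Markers counted as raised in a cluster at 2-fold or more over the median cluster with a mean of at least 0.05, and a name needed at least 3. A cluster also stayed unnamed where its top 10 genes held at least 1 marker of another cell family and as many as of its own.

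The expected log2 ratio weights the pooled cluster means by the estimated nuclei, so it takes up part of any change within clusters, and its subtraction removes that part too. Some choices were made after the data were examined. These were the pseudocount, the scoring rule for cluster names, the estimate of nuclei per cluster and library, the log2 ratio expected from those nuclei, and 3 added gene lists. The naming rule was revised after a first version had named clusters 17, 21 and 22 against their leading genes. For the share of nuclei, 3 estimators were tried: the 9336 values above, the 1490 of them from genes listed in only 1 cluster, and a bounded least squares fit that assumes equal cluster profiles in both libraries, tried with 2 weightings of which 1 is given. The first is reported because it was tested on simulated data. The others were not, so that test does not rank the 3 estimators. The first does not need equal whole profiles. It does assume that the rare genes used hold equal parts of a cluster's signal in both libraries, up to a common factor. Alternatives planned or added covered the filter, the scaling between libraries, the pseudocount, the fold threshold, the list summary, the matching of random lists, the denominator of shares and the share estimator.

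The calculation was tested on simulated nuclei for 31053 genes with known numbers, depths and 200 changed genes. The simulated shares and depths were taken from the estimates. Both libraries of a cluster were drawn from the same pooled profile, apart from the changed genes. The simulation therefore cannot show errors that arise where cluster profiles differ between the libraries. The numbers of nuclei were recovered exactly, and the true share lay in its interval for 23 of 23 clusters. The largest error was 11.9 percentage points among clusters of more than 100 nuclei. An error of this size exceeds the reach of the reported interval of any such cluster, for example 77.6% to 84.8% for cluster 4. The simulated coverage therefore does not vouch for the width of the reported intervals. The depth estimate was 3266 against a true 3266 UMIs for the library labelled knockout and 4014 against 4026 for the other. It replaced a first estimator that had come out too low. The true ratio lay in its interval for 95.1% of 11803 unchanged genes. For the 50 genes of each size it did so for 94% at 0.25-fold, 98% at 0.5-fold, 100% at 2-fold and 94% at 4-fold. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.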

Results

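Gene expression was measured in single nuclei of the medial prefrontal cortex of male mice labelled as knockout for the clock transcription factor NPAS2 or as wild-type littermates. Tissue was taken at zeitgeber time 20, 20 h after lights on in a cycle with 12 h of light. The series concerns NPAS2, dopamine synthesis in this region and napping. There was 1 library per genotype, each a pool of 4 mice, so no value below has a replicate check. The library labelled knockout held 7161 nuclei (56.2%) and the library labelled wild-type 5578 (43.8%). Their estimated depths were 3274 and 4034 UMIs per nucleus, and 3 UMIs correspond to a mean of 0.00128 and 0.00133 counts per 10000. Values below are means of counts per 10000 counts of a nucleus, and ranges in parentheses are 95% counting intervals unless stated otherwise.

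Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236, plus strand, mm10) was not lower in the library labelled knockout. Its mean was 1.39 there and 1.29 in the library labelled wild-type, a ratio of 1.08 (1.02 to 1.15) and a log2 ratio of 0.11. Of its signal, 21.6% lay in cluster 0, 16.2% in cluster 1 and 13.5% in cluster 6. The nearby genes Rpl31 and Tbc1d8 had log2 ratios of -0.30 and -0.29, and the list of genes near Npas2, with Npas2 itself among its 3 members above the floor, had a median of -0.29 at percentile 6.76 of random lists. That median became 0.026, at percentile 63.8, after subtraction of the value expected from nuclei per cluster. The allele and the deleted part of the gene are not given in the sources used here, and a 3' tag outside the deleted part checks nothing. The genotype is therefore named by the library's label throughout, and every direction below rests on that label.

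The authors' 23 clusters were described with marker lists fixed before the data were examined. Cluster 6 (683 nuclei) raised all 12 markers of striatal spiny projection neurons, cells of a neighbouring region, with Rarb, Rgs9 and Drd2 among its leading genes. Cluster 8 (474 nuclei) was oligodendrocyte-like with 9 of 9 markers raised, and cluster 18 (191 nuclei) microglia-like with 10 of 10. Cluster 14 (270 nuclei) raised 9 of 9 astrocyte markers and also 8 of 8 endothelial markers. Cluster 19 (187 nuclei) was of the oligodendrocyte lineage, with 9 of 9 oligodendrocyte and 8 of 8 precursor markers raised and Pdgfra, Bcas1 and Vcan in the lead. Clusters 0, 1, 2, 5, 7, 15, 16 and 20 were excitatory-like, among them clusters 2 and 16 with layer 6 markers. Clusters 4, 9, 10, 11, 12 and 13 were inhibitory-like, with Vip leading cluster 12 and Sst cluster 13. Clusters 3, 17, 21 and 22 stayed unnamed. Clusters 21 (37 nuclei) and 22 (20 nuclei) raised markers of 2 cell families each.

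The libraries differed in how their nuclei fell into these clusters. Cluster 6 took 10.4% of the library labelled wild-type (9.96 to 10.9, resampling of genes) and 1.41% of the library labelled knockout (1.06 to 1.78). The non-neuronal clusters 8, 14, 18 and 19 together took 14.1% (13.5 to 14.7) and 4.67% (4.22 to 5.16). Cluster 4, led by Adamts19, Cpa6 and Dnah11, took 3.33% and 11.3%. Clusters 4, 10 and 17 together took 7.16% of the library labelled wild-type (6.37 to 7.997) and 17.2% of the library labelled knockout (16.5 to 17.8). Cluster 3 took 5.75% and 10.5%, with 70.1% of its nuclei in the library labelled knockout, or 84.3% by least squares. A least squares estimate placed all nuclei of cluster 4 (100%) in the library labelled knockout, where the reported estimate placed 81.3% (77.6 to 84.8) and genes of 1 cluster only placed 70.4% (57.8 to 82.3), a share ratio of 1.85 against 3.39. Least squares also turned the direction of cluster 10 and gave share ratios of 0.138, 0.139 and 0.178 for clusters 8, 14 and 18, against 0.319, 0.331 and 0.336. For cluster 8, genes of 1 cluster only gave 0.568, with an interval of its knockout share (25.6% to 58.3%) that held that library's share of all nuclei. Genes that define a cluster also differed between the libraries, so cluster sizes and gene levels are not separate results, and a cluster mostly of 1 library may reflect that library.

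**Figure D1:**
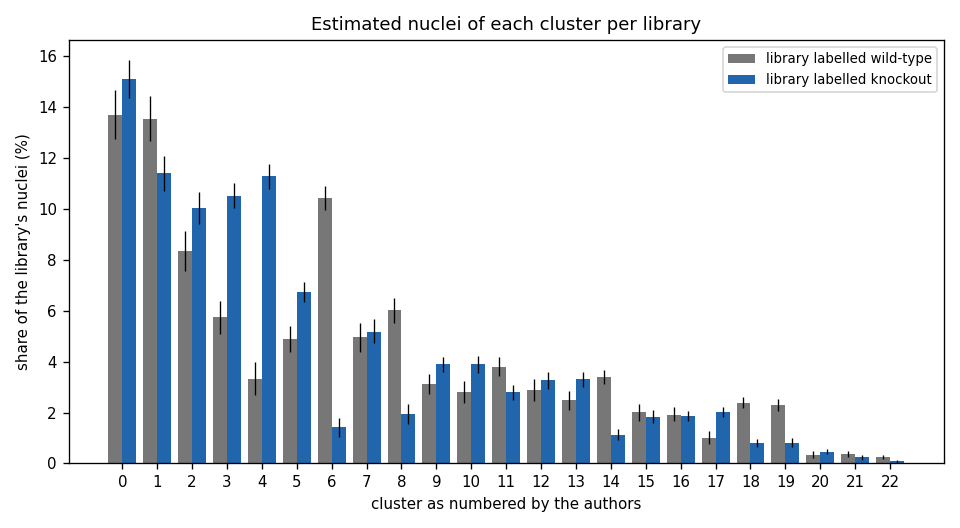
Estimated share of each library's nuclei (%, bars from 0) in each of the authors' 23 clusters, for the library labelled wild-type (grey) and the library labelled knockout (blue), with error bars giving 95% intervals from resampling of genes. Cluster 6 took 10.4% and 1.41%, and cluster 4 took 3.33% and 11.3%.

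Of 12003 genes above the floor, 68 were at least 2-fold higher and 284 at least 2-fold lower in the library labelled knockout, and the median log2 ratio of all was -0.06. The 12 largest named decreases included striatal genes. Drd2, a dopamine receptor, was 7.58-fold lower (5.46 to 10.8) and Sh3rf2 9.69-fold lower (6.34 to 15.4). Rarb, a retinoic acid receptor, was 4.75-fold lower and the sodium channel subunit Scn4b 7.28-fold lower. Glial genes were among them as well. Opalin, a protein of myelinating oligodendrocytes, was 6.29-fold lower (5.08 to 7.86), the oligodendrocyte transcription factor Nkx6-2 7.53-fold lower, and the thyroid hormone transporter Slco1c1 5.82-fold lower (4.46 to 7.69). The mitochondrial genes mt-Nd4l, mt-Atp6 and mt-Nd2 were 5.28-fold, 4.71-fold and 4.72-fold lower. Omg (chromosome 11, 79500982 to 79504084), which encodes a myelin-associated glycoprotein, had the largest log2 decrease among genes with an assigned name, with means of 0.407 and 0.0146, 28.0-fold lower (18.8 to 43.4). Strain variants and annotation at this gene were not examined.

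The 12 largest named increases each had their largest signal in cluster 4, 10 or 17. Vipr2, a receptor for vasoactive intestinal peptide, was 24.2-fold higher (14.6 to 43.4) in the library labelled knockout, and Trh, which encodes thyrotropin-releasing hormone, 18.2-fold higher (10.1 to 36.6). Dnah11, Frmd7, Cdhr1 and Adamts19 were 14.6-fold, 14.3-fold, 13.5-fold and 13.1-fold higher. Npffr2, a neuropeptide FF receptor, Lgr6, Lgr5 and Cpa6 were 10.8-fold, 10.5-fold, 10.5-fold and 9.34-fold higher. Trdn and Shisa8 were 6.84-fold and 6.52-fold higher.

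Genes at least 2-fold apart lay mainly in the clusters whose shares differed. Of the 284 lower genes, 251 (88.4%) had their largest signal in cluster 6 or a non-neuronal cluster, against 8.33% of all genes above the floor. Of the 68 higher genes, 52 (76.5%) had it in clusters 4, 10 or 17, against 8.49%. Cluster 4 alone led 47 of the 52, cluster 17 led 3 and cluster 10 led 2. Cluster 10 also led 4 of the lower genes and cluster 4 led 1. The log2 ratio expected from the nuclei per cluster had the sign of the observed one for 347 of these 352 genes (98.6%), against 76.6% of the genes less than 2-fold apart. The cluster means behind the expected value pool both libraries and so contain each gene's own change, which by construction raises this agreement and the correlation that follows. Across the 12003 genes, which are not independent replicates, the correlation of expected and observed values was 0.78 (Pearson) and 0.72 (Spearman). After the expected value was subtracted, a step chosen after the data were seen, 32 genes were at least 2-fold higher and 39 lower. A pseudocount of 0.1 left 32 and 86, and a pseudocount of 1 left 3 and 11.

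**Figure D2:**
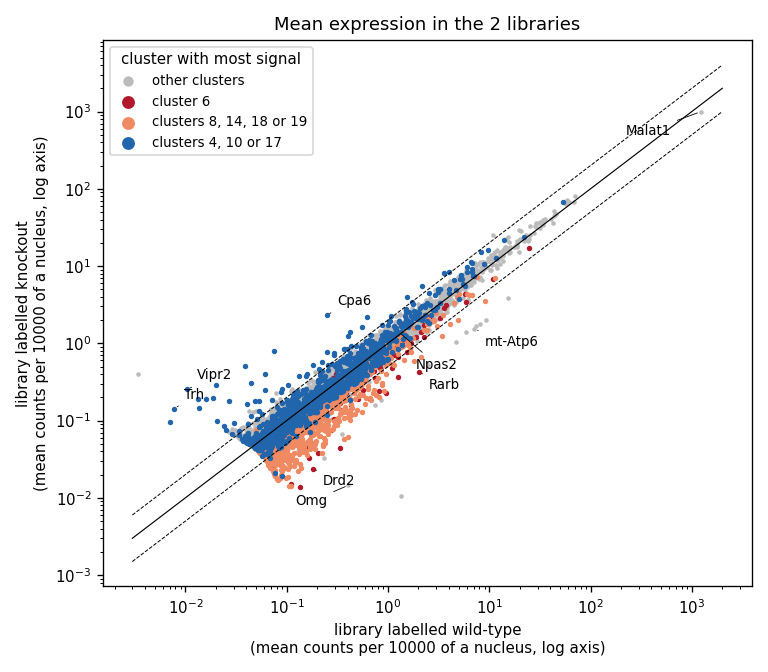
Mean of each gene above the floor in the library labelled wild-type (x) and the library labelled knockout (y), in counts per 10000 of a nucleus on log axes, coloured by the cluster with most of its signal, with a solid line at equal means and dashed lines at 2-fold. Drd2 and Rarb lie below the lower dashed line and Vipr2 and Cpa6 above the upper one, while Npas2 (1.29 and 1.39) lies near the solid line.

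Dopamine receptor and signalling genes were lower in the library labelled knockout. Of the 7 list members above the floor, 6 were lower, and the median log2 ratio was -0.98, below all 10000 random lists. Drd1, Drd2 and Ppp1r1b also stand on the striatal marker list, so these lists are not separate results. Adcy5, Gnal and Pde1b also had their largest signal in cluster 6. Drd2 (chromosome 9, 49340627 to 49408177) had means of 0.182 in the library labelled wild-type and 0.0240 in the library labelled knockout, and Drd1 of 0.222 and 0.108, 2.06-fold lower (1.72 to 2.48). Ppp1r1b, which encodes the dopamine-regulated phosphoprotein DARPP-32, was 3.67-fold lower (2.83 to 4.81) and the adenylate cyclase Adcy5 2.32-fold lower. Gnal and Pde1b had log2 ratios of -0.75 and -0.73, while Pde10a was 1.16-fold higher (1.13 to 1.19). Drd3, below the floor and named after its values were seen, had means of 0.0686 and 0.00622. Cluster 6 held 79.3% of the Drd2 signal and 33.9% of that of Drd1. The list's median was -0.21 after subtraction of the value expected from nuclei per cluster. Subtraction left Drd2 at -0.67, Ppp1r1b at -0.62, Drd1 at -0.25, Adcy5 at -0.21, Gnal at -0.12 and Pde10a at 0.46. The sign of Pde1b turned, to 0.021.

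Dopamine synthesis genes above the floor were also lower, except that the enzyme for the rate-limiting step lay below the floor. Qdpr, Spr and Pts, which make or regenerate the tetrahydrobiopterin cofactor, were 2.04-fold (1.75 to 2.37), 1.83-fold (1.32 to 2.56) and 1.52-fold lower (1.27 to 1.81). Their median of -0.72 lay at percentile 1.11 of random lists, and cluster 8 held 45.4% of the Qdpr signal. Without the floor the median over all 9 listed genes was -0.03, and the percentile was 3.38 after subtraction of the expected value. Th (chromosome 7, 142892752 to 142931128), the rate-limiting enzyme, had a mean of 0.0468 in the library labelled knockout and 0.00671 in the library labelled wild-type, a ratio of 6.97 (3.58 to 15.2) on about 110 and 15 UMIs. Ddc, the next enzyme, had means of 0.0147 and 0.0317, and Gch1 of 0.00423 and 0.00320. Cluster 8 held 45.1% of the Ddc signal. The Ddc log2 ratio was -0.76 on about 34 and 71 UMIs, against -0.64 expected from nuclei per cluster. Th, Ddc and Gch1 were named after their values were seen. Clusters 4 and 10 held 77.3% of all Th signal, and at least 67.3% of it came from their nuclei in the library labelled knockout. Outside these clusters the mean of Th in that library was at most 0.0139.

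**Figure D3:**
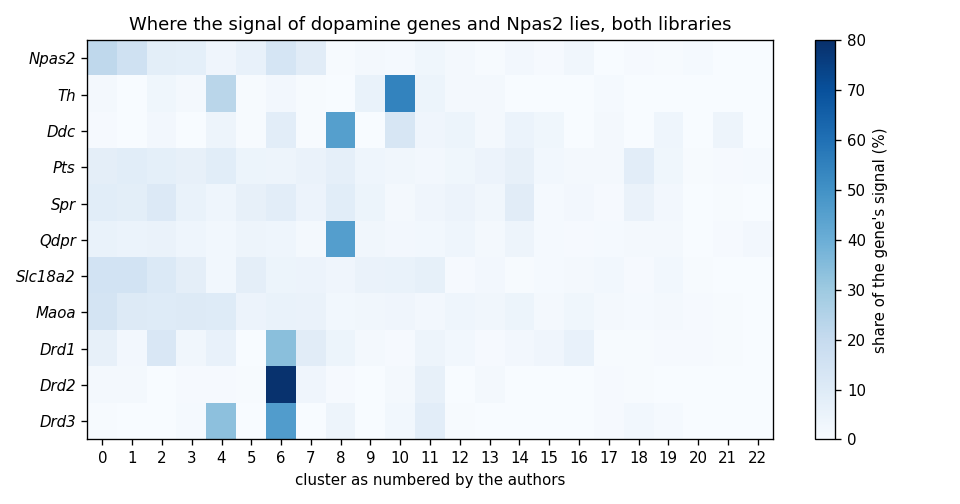
Share of each gene's signal (%, colour scale from 0 to 80) by cluster, both libraries pooled, for Npas2 and genes of dopamine synthesis, breakdown, transport and reception. Cluster 6 held 79.3% of the Drd2 signal, cluster 10 held 54.3% of that of Th and cluster 8 held 45.4% of that of Qdpr.

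Dopamine transport and breakdown genes differed less. The 4 members above the floor had a median log2 ratio of -0.14, at percentile 40.0. Maob was 1.39-fold lower (1.01 to 1.92). Maoa had a ratio of 1.02 (0.883 to 1.18), and Slc18a2, the vesicular monoamine transporter, one of 0.949 (0.772 to 1.17).

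Core clock genes did not move together. Of 19 members above the floor, 6 were higher and 13 lower, with a median of -0.04 at percentile 53.4 that became 0.02 under scaling to the median ratio. Arntl, the partner of NPAS2 and CLOCK, was 1.43-fold higher in the library labelled knockout (1.32 to 1.55), and Per2 1.45-fold higher (1.23 to 1.72). Nr1d2 was 1.29-fold lower (1.16 to 1.44), Cry2 1.17-fold lower (1.05 to 1.30), Csnk1e 1.16-fold lower (1.01 to 1.32) and Rora 1.14-fold lower (1.11 to 1.17), while Rorb had a ratio of 0.911 (0.871 to 0.953). Clock had a ratio of 0.977 (0.912 to 1.05), Per1 of 0.972 (0.798 to 1.18) and Per3 of 0.970 (0.888 to 1.06), and these, like Bhlhe40 and Bhlhe41, changed sign on the log2 scale under that scaling. The intervals of Cry1, Csnk1d, Nfil3, Nr1d1, Ciart, Bhlhe40 and Bhlhe41 also held 1. Of 7 clock-controlled output genes, 6 were lower, with a median of -0.24 at percentile 8.83. Dbp, a direct target of the clock, was 2.18-fold lower (1.67 to 2.85), Tef 1.43-fold lower, Usp2 1.43-fold lower and Hlf 1.19-fold lower. The log2 ratios of Hlf, Rora and Rorb (-0.24, -0.19 and -0.13) lay near those expected from nuclei per cluster (-0.22, -0.16 and -0.16). Dbp had -0.99 against -0.35 expected, Tef -0.50 against -0.17 and Usp2 -0.51 against -0.08. Nr1d2 had -0.36 against -0.10, Cry2 -0.22 against 0.03, Arntl 0.51 against -0.01 and Per2 0.51 against -0.03.

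Mitochondrially encoded transcripts were lower as a group. All 12 members above the floor were at least 2-fold lower, with log2 ratios from -2.24 to -1.99 and a median of -2.15, below all random lists. The mean of mt-Co3 was 9.25 in the library labelled wild-type and 2.001 in the library labelled knockout. Immediate early genes were lower for 15 of 17 members, with a median of -0.38 at percentile 0.16. Junb was 1.65-fold lower (1.45 to 1.88), Egr4 1.65-fold, Btg2 1.58-fold and Jund 1.51-fold. By the mean of the list the percentile was 2.86. All 10 heat shock and stress genes were lower, with a median of -0.40 at percentile 0.1, among them Hsp90ab1 (1.502-fold), Hspe1 (1.47-fold), Hspd1 (1.46-fold) and Hspa8 (1.42-fold). Ribosomal protein genes were also lower (74 of 76, median -0.50), as were nuclear genes of the respiratory chain (66 of 70, -0.33). Both lists were written after the data were examined. None of their members was at least 2-fold lower, whereas all 12 mitochondrially encoded ones were. Of the nuclear retained RNAs, Malat1 was 1.23-fold lower (1220 and 994) and Neat1 3.71-fold lower, Snhg11 was 1.14-fold and Mirg 1.29-fold higher, and the median was 0.07 at percentile 55.1. The sex-linked check had 4 members above the floor, Ddx3y, Uty, Kdm5d and Eif2s3y, with log2 ratios from -0.13 to -0.01 and a median of -0.03 at percentile 47.0, which was 0.04 under scaling to the median ratio.

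Glutamate receptor genes were higher for 20 of 21 members, with a median of 0.29 at percentile 99.95. Gria1 was 1.47-fold higher (1.43 to 1.51), Grm4 1.52-fold and Grm8 1.46-fold, whereas Grm3 was 1.70-fold lower (1.65 to 1.76). The Grm3 signal lay most in clusters 0 (24.0%), 2 (13.8%) and 6 (9.64%). Genes of GABA synthesis, transport and reception were lower for 12 of 20 members, with a median of -0.11 at percentile 2.19, but at 26.9 among unmatched lists, 20.4 by the mean of the list and 2.77 after subtraction of the expected value. Gad1 was 1.67-fold and Gabra5 1.58-fold higher, and Gabrg3 1.60-fold and Gabrg1 1.53-fold lower. Arousal neuromodulator receptors had a median of -0.09 at percentile 33.1, with Chrm2, a muscarinic receptor, 2.98-fold higher (2.75 to 3.22) and Htr4 2.13-fold, Adra2c 1.75-fold and Htr1b 1.74-fold lower. Sleep need genes had a median of 0.04 at percentile 81.7, with Cacna1h (1.61-fold), Cacna1g (1.34-fold) and Kcnn2 (1.31-fold) higher and Adora1 1.49-fold lower. Of the glial reactivity list, 3 members were above the floor, Apoe (2.37-fold lower), Trem2 (2.31-fold) and Tyrobp (1.42-fold), with a median of -1.08 at percentile 0.1. The median expected from nuclei per cluster was -0.52, and that of the list without the floor was -0.32.

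Marker lists of cell types differed as follows. Striatal markers had a median log2 ratio of -1.46 (8 of 10 lower), oligodendrocyte markers of -1.57 (9 of 9), differentiating oligodendrocyte markers of -1.44 (4 of 4), precursor markers of -1.14 (5 of 6), astrocyte markers of -0.999 (6 of 6) and microglia markers of -0.88 (9 of 9), each below all random lists. After subtraction of the expected value the differentiating oligodendrocyte list lay at percentile 7.17, with a median of -0.25. The striatal (-0.50) and oligodendrocyte (-0.57) lists stayed below all random lists, and the precursor (-0.36), astrocyte (-0.33) and microglia (-0.29) lists at percentiles 0.18, 0.06 and 0.12. These values used the reported shares only. Least squares placed fewer nuclei of clusters 6, 8, 14, 18 and 19 in the library labelled knockout. Genes of 1 cluster only placed more of clusters 8 and 14 there and fewer of 6, 18 and 19. Random lists were not matched on leading cluster, so an error in a cluster's share would shift its whole marker list. A lower level per nucleus therefore cannot be read from these values. Erythrocyte markers had a median of -1.04 (3 of 4 lower) at percentile 0.08. Among neuronal lists the medians were 0.18 for excitatory neurons (percentile 95.1), -0.13 for upper layers (13.1), 0.25 for layer 5 (99.6) and 0.18 for layer 6 (93.7). They were 0.24 for inhibitory neurons (99.1), 0.26 for Pvalb (97.6), 0.51 for Sst (99.9, with a median of 0.18 without the floor), 0.08 for Vip (85.9) and -0.10 for Lamp5/Sncg interneurons (24.8). Within the Sst list, Sst itself had a log2 ratio of -0.06 and Npy of 0.16, while Elfn1 and Nos1 had 0.86 and 1.06. By the mean of the list the percentile was 96.6 for layer 5, 12.7 for Pvalb and 98.8 for Vip. The Pvalb list had a mean of -0.25, with Tac1 at -1.74, and the inhibitory list a median of -0.0096 after subtraction of the expected value. Subtraction also put the percentile at 49.2 for inhibitory neurons, 78.7 for Pvalb and 95.9 for layer 5, and left Sst at 99.8 with a median of 0.39. Cluster 11, which raised 5 Sst interneuron markers, had a share ratio of 0.733 (0.597 to 0.892, resampling of genes). Its knockout share was 48.5%, against 18.4% by least squares and 44.2% (30.9% to 57.4%) by genes of 1 cluster only. The last interval held that library's share of all nuclei. Members above the floor were too few for a median in the endothelial (1), pericyte and smooth muscle (2), leptomeningeal (1), T cell (2), perivascular macrophage (0) and ependymal (0) lists.

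**Figure D4:**
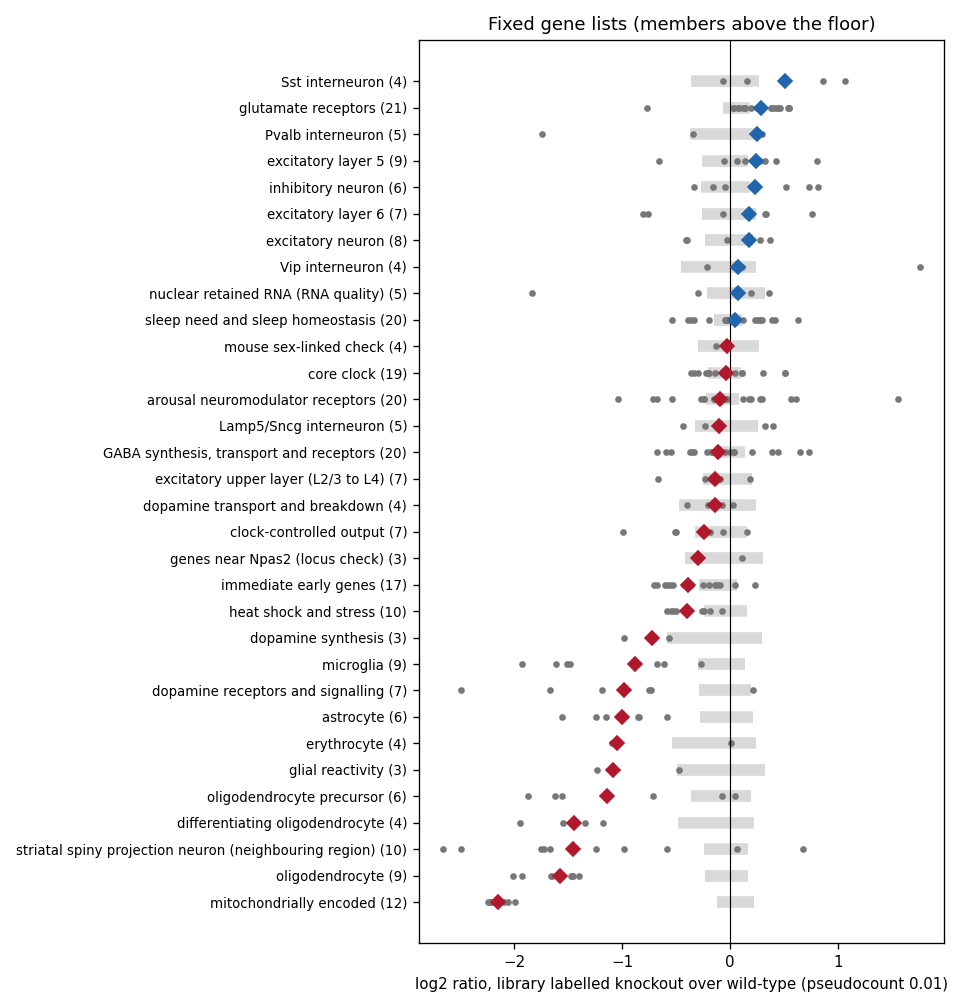
Log2 ratio of the library labelled knockout over the library labelled wild-type for the members above the floor (grey points, number in parentheses) and the median (diamond, red below 0 and blue above) of each fixed list, with a grey band for 95% of the medians of matched random lists. The mitochondrially encoded list has the lowest median (-2.15) and the Sst interneuron list the highest (0.51) among members above the floor.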

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

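Subtraction of the value expected from nuclei per cluster, the share estimators other than the reported one, the removal of Malat1 and mitochondrial genes from the total and the 1.5-fold marker threshold were chosen after seeing the data. Where values moved, the cause was not tested, except that a filter, floor, threshold or pseudocount acts by its own construction. At the 1.5-fold marker threshold cluster 14, counted above among the non-neuronal clusters, became unnamed. Cluster 3 was then named excitatory upper layer and cluster 17 Lamp5/Sncg interneuron. The best class of cluster 11 moved from Sst interneuron to inhibitory neuron, and the other names held. Genes at least 2-fold higher or lower (68 and 284) numbered 518 lower without a filter, 179 lower at the doubled floor, 32 and 86 at pseudocount 0.1, 3 and 11 at pseudocount 1, and 350 and 829 at 1.5-fold. They numbered 32 and 39 after subtraction of the expected value, or 40 and 66 with shares from genes of 1 cluster only, and the share of lower genes was then 54.9% and 62.3% against 80.7%. That share was 70.3% at 1.5-fold. For the list medians that follow, subtraction used the reported shares only. Subtraction moved list medians to -0.082 (upper layers), -0.0096 (inhibitory neurons, reversed), -0.50 (striatal), -0.33 (astrocyte), -0.57 (oligodendrocyte), -0.25 (differentiating oligodendrocyte), -0.29 (microglia), -0.35 (dopamine synthesis), -0.21 (dopamine receptors), -1.92 (mitochondrially encoded) and -0.0016 (sex-linked), and the Npas2 log2 ratio to 0.33. It also changed other medians, by less than the resampling spread of the list: to -0.36 (oligodendrocyte precursor), -0.51 (glial reactivity), -0.68 (erythrocyte), -0.23 (heat shock), 0.072 (Pvalb), 0.12 (layer 5), 0.074 (excitatory) and 0.19 (glutamate receptors). The sign turned for genes near Npas2 (0.026), core clock (0.021) and nuclear retained RNA (-0.0105). Percentiles left the outer 2.5% for layer 5 (95.9), inhibitory neurons (49.2), Pvalb (78.7), differentiating oligodendrocyte (7.17), dopamine synthesis (3.38) and GABA (2.77). Scaling to the median ratio gave -0.070 for upper layers, 0.32 for Pvalb, -2.08 for mitochondrially encoded and 0.037 for sex-linked genes. Without a filter the medians were -0.034 for dopamine synthesis and -0.32 for glial reactivity, and, within the spread of the list, 0.18 for Sst, 0.33 for layer 6, -0.37 for clock-controlled output, -0.19 for genes near Npas2, -0.081 for sex-linked genes and 0.027 for Lamp5/Sncg, whose sign turned. The mean of the Pvalb list was -0.25, against a median of 0.26.

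Ratios of cluster shares depended on the denominator and the estimator. Among non-neuronal nuclei only, the ratios of clusters 8, 14, 18 and 19 were 0.965, 0.9998, 1.01 and 1.08, against 0.319, 0.331, 0.336 and 0.357 over all nuclei, with the reported estimator. With genes of 1 cluster only, clusters 4, 8 and 19 had ratios of 1.85, 0.568 and 0.2498, against 3.39, 0.319 and 0.357. Least squares gave 0.138, 0.139 and 0.178 for clusters 8, 14 and 18, and 0.848 for cluster 10 against 1.38, and placed clusters 4, 6 and 17 wholly in 1 library, which gives no ratio. The authors' p thresholds, the detection filters, the filter on genes per nucleus, the ranking by detection share and the authors' own marker threshold were not run, since the table has no such values. No paired analysis was possible because each genotype had 1 pooled library and no test was made. Depth limits genes near the floor, such as Th with about 15 UMIs in the library labelled wild-type.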

Other observations

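The tests below were chosen only after the results were seen, except that of ribosomal protein genes, and the lists of olfactory bulb, ribosomal protein and respiratory chain genes were written after the data were examined. Beyond the fixed lists, 74 of 76 ribosomal protein genes were lower in the library labelled knockout, with a median log2 ratio of -0.50. Nuclear genes of the respiratory chain were lower for 66 of 70 members, with a median of -0.33. Both medians lay below all random lists.

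A few features, singled out after their values were seen, differed many-fold and had signal in nearly all clusters. Gm47283 (chromosome Y, 90784738 to 90816464), annotated as protein-coding, had means of 1.34 in the library labelled wild-type and 0.0106 in the library labelled knockout, 127-fold lower (80.4 to 212) in the latter. AC161816.1 (chromosome 16, 39446749 to 39488234), a long intergenic RNA, had means of 0.00338 and 0.395, 117-fold higher (49.6 to 367). Omg was 28.0-fold lower. These 3 features had signal in 23, 22 and 22 of the 23 clusters. Whether strain variants or annotation shape these ratios was not tested, and no reads were analysed. Cluster 10, which held most of the Th signal, was led by Igfbpl1, Pax6, Dlx6os1 and Top2a among others, and the unnamed cluster 17 by Olfr111, Vmn1r209 and Cdhr1.

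Striatal markers and dopamine receptor genes were lower in the library labelled knockout. Fewer striatal-like nuclei may account for part of this: 14.8% of cluster 6 nuclei came from that library (11.1 to 18.6), against 56.2% of all nuclei. Such a difference could come from the dissection of the tissue or from the mice, which 1 pool per genotype cannot separate. Whatever the split of the cluster 6 signal, and within the interval of its nuclei, the ratio outside cluster 6 was under 1 by more than counting error for 3 of 14 genes, among them Penk (at most 0.484) and Pdyn (at most 0.758), and over 1 for Meis2 (at least 1.18). For Drd1 the upper bound was 0.980, or 1.24 with counting error. A lower level per nucleus after loss of Npas2 therefore cannot be told apart from other sources for the set, since the table does not divide a cluster by library.

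Th and 52 genes with most signal in clusters 4, 10 and 17 were at least 2-fold higher in the library labelled knockout. Of the 52, 47 had it in cluster 4. These 53 genes were selected for being higher. All 1019 genes above the floor with most signal in clusters 4, 10 and 17 had a median log2 ratio of 0.058. The value expected from nuclei per cluster was 0.031, so the median of the whole group lay near expectation. For the selected genes, numbers of nuclei per cluster alone were argued against. Counting intervals were widened for the choice among 1020 genes, in place of the unwidened ones first used. The expected log2 ratio lay under the interval for 48 of the 53 even at the upper ends of the shares, and for 31 of 53 with least squares shares (Th 2.80 observed, 0.86 and 0.41 expected). Among all 1019 genes, at the upper ends, 132 lay above expectation by that measure and 93 below. The expected value takes each cluster to hold the same mix of cells in both libraries. Different numbers of subtypes within a cluster were therefore not tested. Nuclei from the olfactory bulb are a candidate source, since all 13 measured bulb genes above the floor of 16 listed were higher, such as Meis2 (6.09 and 9.77), Synpr (1.71 and 3.44) and Etv1 (1.03 and 1.39), but 9 of the 16 had values that were seen before the list was written and 5 stand on other lists. The test was then repeated on the 4 others, whose median of 0.60 lay at percentile 97.8 of lists from the same clusters, just past the bound set for it. Their values too had been seen by then, so it decides nothing, and an effect of genotype on these nuclei stays open and untested.

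Mitochondrially encoded transcripts were lower by a median of -2.15. Numbers of nuclei per cluster gave an expected median of -0.22, above the highest member (-1.99), and leaving Malat1 and mitochondrial genes out of the totals gave -2.19, so neither accounts for it. Less cytoplasmic RNA carried over with the nuclei of that library may contribute. The median of ribosomal protein genes, -0.5001, passed the bound of -0.5 set beforehand by less than its spread (-0.54 to -0.41). It was -0.44 under scaling to the median ratio and -0.37 after subtraction of the value expected from nuclei per cluster. Of the nuclear retained RNAs, Malat1 was lower (1220 and 994) and 3 of 5 members were higher, with the list's median at percentile 55.1. Carry-over and other sources therefore cannot be told apart on these values. A genotype effect on mitochondria stays open and untested.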
